A study of Homo sapiens with 8 samples.

How the data were processed

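The series measured RNA in HEK293 cells, a human embryonic kidney cell line, that stably express La fused to green fluorescent protein (gfp). La is an RNA-binding protein encoded by SSB. One line expresses wild-type gfp-La and the other the sumoylation-deficient mutant K41/200R, in which the lysines at positions 41 and 200 are replaced by arginine. From each line the labels give 2 libraries of input RNA and 2 of RNA recovered by immunoprecipitation with an antibody against gfp (RNA immunoprecipitation followed by sequencing), which makes 4 groups of 2 and 8 libraries in all. Libraries were made with the TruSeq RNA Sample Prep Kit, per the labels' protocols. The labels also mention a line that expresses gfp alone. No library from it was analysed here, so the background of the immunoprecipitation is not measured in what follows. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

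The authors deposited 1 table per line with raw counts of reads per gene, together with their own log2 fold change of immunoprecipitate over input, its standard error, a Wald score and p-values before and after adjustment, per the file headers. TopHat2, HTSeq, DESeq2 and the genome build hg19 are named, without versions, in the submitters' processing notes. The gene annotation and whether counting used strand are not given in the sources used here, so overlapping genes and antisense partners could not be told apart. Each table lists 19088 gene rows, which hold protein-coding genes. Of the 23 gene lists fixed for this work, 6 had 0 members in the tables, among them the RNA polymerase III transcripts, small nuclear RNAs and small nucleolar RNAs, so the small RNAs that La is known to bind were not analysed here. Neither table gives coordinates, and none are printed. Symbols were taken from the column beside the counts. A further symbol column in the tables differs from it in 2428 rows and was not used. Rows of column sums and of HTSeq's classes stayed out of library sizes and tests. In the wild-type table reads assigned to genes were 29.9% and 29.5% of the recorded reads for the input samples and 30.4% and 40.8% for the immunoprecipitates. Reads outside any feature were 39.4%, 59.3%, 48.3% and 53.1% of the same libraries, ambiguous reads 0.282%, 0.247%, 0.0978% and 0.127%, and reads with more than one alignment 30.4%, 10.9%, 21.2% and 5.92%.

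Counts from both tables were joined by symbol and analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 13657 genes, and libraries were scaled by TMM. All 8 libraries entered 1 quasi-likelihood fit of group means with 4 residual degrees of freedom. The comparisons were immunoprecipitate against input for each protein, the difference between these enrichments (mutant minus wild type), input against input and immunoprecipitate against immunoprecipitate. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Log2 fold changes are given with their standard error (SE), and levels as CPM, counts scaled by the effective library size, with the SD over n = 2 libraries. Gene lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the 17 lists with at least 3 tested genes. The authors' deposited fold changes and adjusted p-values are quoted only where named as theirs.

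Total counts ranged from 8965224 to 20978045 per library. Replicates were checked for duplication by a chi-square test over genes with a summed count of at least 20. The statistic was 40.6 to 183 per degree of freedom, so no library was a copy of the other one in its group. Intervals and floors for genes with few counts cover counting error at the 95% level only, with a floor of 3 counts over the group. The procedure was tested on simulated counts for the 13657 genes with known changes. For wild-type immunoprecipitate against input it recovered 1 of 60 genes changed 2-fold, 38 of 70 changed 4-fold and 67 of 70 changed 16-fold. For the difference of enrichment it recovered 1 of 60, 5 of 70 and 58 of 70, and for input against input 4 of 60, 38 of 70 and 67 of 70. For wild-type immunoprecipitate against input the simulation called 110 genes in all, against 4226 in the data. Adjustment was thus stricter in the simulation, whose recovery can understate that of the tests of immunoprecipitate against input.

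Named genes followed a rule fixed before the data were examined, as were the lists, the tests and the alternatives other than those named below as added. The rule took the 10 largest called changes in each direction among genes with a mean of at least 10 CPM and no overlap between the libraries compared, or, where fewer than 5 passed, the 5 of smallest p. It added SSB, the mRNAs linked to La and up to 4 members of each list, and the text prints part of them. One result that the rule would name is not reported here. Alternatives were DESeq2 1.42.0, other scalings, other filters on low counts, each library left out in turn, a minimum fold of 1.5, a fit with only the groups compared, and the sample number as a block. Corrections for transcript length and GC content, and a fit without both wild-type libraries numbered 1, were added after seeing the data. Transcript length is the median over protein-coding transcripts in GENCODE 29, which is on another build than the counts and was used only for lengths, GC content and gene order. Of the 19088 gene rows 17556 matched by symbol, 1183 by synonym in RefSeq and 349 not at all, and 99.2% of the tested genes had a length.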

Results

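RNA bound to gfp-tagged La was compared with input RNA in HEK293 lines expressing the wild-type protein or the sumoylation-deficient mutant K41/200R. The series asks how RNA binding differs between the 2 proteins, as part of the role of La sumoylation in the cell. Total counts over genes were 20978045 and 19277709 for wild-type input, 11740481 and 16408094 for the wild-type immunoprecipitate, 19565542 and 11242626 for mutant input, and 8965224 and 14601014 for the mutant immunoprecipitate. EEF1A1, a translation elongation factor, took the most counts in 6 of the 8 libraries, 1.08% to 2.10% of the total. AHNAK led in the second wild-type immunoprecipitate with 2.12%, and USP9X in the second mutant one with 0.951%. On principal components of log2 CPM the first component, 57.1% of the variance, separated immunoprecipitates from inputs. On the second, 26.5% of the variance, the wild-type samples numbered 1 lay at 6.16 (input) and 7.55 (immunoprecipitate), between those numbered 2, at 75.1 and 81.8, and the mutant samples. In the same order the mutant samples numbered 1 lay at -52.1 and -54.2, and those numbered 2 at -33.0 and -31.4. Input and immunoprecipitate of the same line and number thus lay close together on it.

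The first comparison asks which mRNAs were recovered with wild-type La. Messages of ribosomal proteins and of the respiratory chain were depleted from the immunoprecipitate, and long messages of matrix and membrane proteins were enriched. Tested as lists, these 3 groups missed the threshold with an estimated correlation (adjusted p = 0.198, 0.198 and 0.0752). They passed directional fry (adjusted p = 0.00278, 0.00286 and 0.00278). RPS12, a protein of the small ribosomal subunit, was at 681.7 ± 68.8 CPM in input and 10.8 ± 1.22 CPM in the immunoprecipitate (SD, n = 2), a log2 change of -5.98 ± 0.36 (SE; edgeR adjusted p = 0.000332). COL1A1, a chain of type I collagen, was at 4.67 ± 1.16 and 56.2 ± 28.1 CPM, a log2 change of 3.59 ± 0.42 (edgeR adjusted p = 0.000745). Of 13657 genes tested, 1785 were higher and 2441 lower in the immunoprecipitate. With library size alone as the scale the split was 744 higher and 3491 lower, and the median of all genes shifted to -0.47. Without the first wild-type input 2599 genes passed and without the second 2549.

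Among 78 tested ribosomal protein mRNAs 0 were higher and 74 lower, 76 when adjusted over the list alone, with a median log2 change of -3.24. RPS29 and RPS15A changed by -5.93 and -5.32. Camera's preset correlation gave an adjusted p of 1.63e-54, but the adjusted p was 0.198 with an estimated correlation. Nuclear-encoded subunits of oxidative phosphorylation (OXPHOS) gave 0 higher and 60 lower of 73 (62 adjusted over the list alone), with a median of -3.03. Among them were NDUFA4 at -6.02, ATP5E at -5.36 and COX6C at -5.15 (list adjusted p = 0.198 with an estimated correlation). Replication-dependent histone mRNAs gave 0 higher and 48 lower of 55 (52 adjusted over the list alone), median -2.34, with HIST1H3B at -3.77 and HIST1H2BJ at -3.69 (list adjusted p = 0.216 with an estimated correlation). Many histone genes are near-identical copies, so their single values are uncertain. Other mRNAs with a 5' terminal oligopyrimidine tract (TOP) gave 2 higher and 8 lower of 22 (3 and 10 adjusted over the list alone), median -0.86, with TPT1 at -3.95 and EEF1B2 at -3.17 (list adjusted p = 0.672 with an estimated correlation). Secretory and membrane mRNAs gave 21 higher and 1 lower of 35 (26 and 2 adjusted over the list alone), median 1.87. HSPG2, the heparan sulfate proteoglycan perlecan, was at 2.51, COL4A2 at 2.48 and LAMA5 at 2.41 (list adjusted p = 0.0752 with an estimated correlation).

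Large increases outside these lists were seen in PLEC (3.39 ± 0.91), EPPK1 (3.21 ± 0.44), BCL9L (3.05 ± 0.65) and FLNC (2.95 ± 0.36), of which PLEC, EPPK1 and FLNC encode large cytoskeletal proteins, and in the chromatin gene SETD1B (2.89 ± 0.42) and TNRC18 (2.82 ± 0.40). Leaving out the second wild-type immunoprecipitate gave 1.77 for PLEC and 2.06 for BCL9L, and leaving out the second wild-type input gave 4.73 and 4.01. Decreases included OST4 at -5.49 and MTRNR2L8 at -5.90. MTRNR2L8 resembles mitochondrial 16S ribosomal RNA in sequence and is uncertain. SSB itself changed by -1.99 ± 0.43 (edgeR adjusted p = 0.00969), and reads of the transgene and of the endogenous gene could not be separated. Of 8 mRNAs linked to La by earlier work, LAMB1, a laminin chain, passed the test at 1.34 ± 0.41 (edgeR adjusted p = 0.0392, 0.00265 to 0.313 over its alternatives), and missed it without either wild-type input, the first wild-type immunoprecipitate or either mutant input. The other 7 did not pass, and lay between -0.35 for MDM2 and 1.10 for HSPA5. In the SUMO pathway, the activating enzyme subunit UBA2 (-1.80) was lower and RANBP2 (1.95) higher, with 2 higher and 5 lower of 18. The remaining lists did not pass camera's test. They included the STAT3 pathway (3 higher and 1 lower of 22, with JAK1 at 1.35, LIFR at 1.57 and PTPN2 at -1.96), proliferation genes (3 and 5 of 29, with MCM6 at 2.03 and PCNA at -2.07), stress response genes (2 and 5 of 23, with SEL1L at 1.70 and ATF4 at -2.08) and cholesterol synthesis (4 and 2 of 15, with SREBF2 at 1.81). They also included interferon response (1 and 3 of 21, with IFIT5 at -1.69), La-related proteins (2 and 3 of 8, with LARP7 at -1.79), heat shock and immediate early genes (4 and 2 of 19, with HSPA1B at 1.72 and HSPB1 at -2.08) and zinc finger mRNAs (39 and 40 of 443, with ZNF646 at 2.27 and ZNF703 at 2.42). Lineage markers of the HEK293 line gave 3 higher and 0 lower of 15, and markers of other cell types 1 higher and 0 lower of 7, the 1 being COL1A1.

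Change followed transcript length. Among 5 classes of equal gene number, genes in the shortest, 177 to 1557 nt, had a median log2 change of -1.38, with 37 higher and 1354 lower calls, and those in the longest had a median of 0.97, with 912 higher and 63 lower. Across 13548 genes, which are not independent replicates, Spearman's rho between length and log2 change was 0.607. With length removed as a trend 2309 genes passed in place of 4226. The ribosomal protein median moved to -1.20, the OXPHOS median to -0.96 and the secretory median to 1.06, and the histone median turned to 0.13, at which the histone and TOP lists missed camera's preset test (adjusted p = 0.869 and 0.176). Of 40 named calls 10 ended when some single library was left out, in ATF4, HSPA1B, JAK1, LAMB1, LIFR, PLEC, RANBP2, SEL1L, SREBF2 (log2 change 1.14 without the first wild-type immunoprecipitate) and ZNF703 (1.27 without the same library and 3.04 without the second wild-type immunoprecipitate), and 12 ended under the length correction, among them EPPK1, HSPG2, LAMA5 and SSB.

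**Figure D1:**
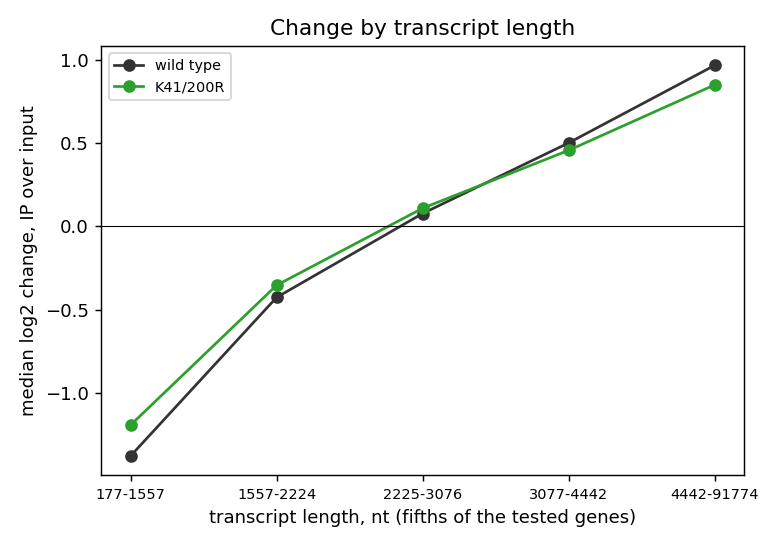
Median log2 change of immunoprecipitate over input (vertical axis) in 5 classes of the tested genes by transcript length in nucleotides (horizontal axis), for wild-type (black) and K41/200R (green) gfp-La. The medians rise from -1.38 and -1.19 in the shortest class to 0.97 and 0.85 in the longest.

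The second comparison asks the same of the mutant. With K41/200R La the same kinds of mRNA stood at both ends. RPS12 was at 632.4 ± 81.1 CPM in input and 11.3 ± 0.565 CPM in the immunoprecipitate, a log2 change of -5.80 ± 0.35 (edgeR adjusted p = 0.000602), and COL1A1 at 6.12 ± 0.753 and 54.1 ± 1.34 CPM, a log2 change of 3.14 ± 0.42 (edgeR adjusted p = 0.00158). In all, 1689 genes were higher and 2223 lower. With library size alone as the scale the split was 685 and 3355, and the median of all genes shifted to -0.45. Without the first mutant input 1073 genes passed, without the second 1567, without the first mutant immunoprecipitate 2406 and without the second 1876.

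Ribosomal protein mRNAs gave 0 higher and 72 lower of 78 (74 adjusted over the list alone), median -2.76, with RPS29 at -5.47 and RPS15A at -5.17 (list adjusted p = 0.299 with an estimated correlation). OXPHOS mRNAs gave 0 higher and 58 lower of 73 (2 and 60 adjusted over the list alone), median -2.42, with NDUFA4 at -5.54, ATP5E at -4.92 and COX6C at -4.90 (list adjusted p = 0.314 with an estimated correlation). Histone mRNAs gave 0 higher and 31 lower of 55 (40 adjusted over the list alone), median -1.66, with HIST1H3B at -2.91 and HIST1H2BJ at -2.98 (list adjusted p = 0.563 with an estimated correlation). Other TOP mRNAs gave 3 higher and 9 lower of 22 (the same adjusted over the list alone), median -0.55, with TPT1 at -3.96 and EEF1B2 at -2.74 (list adjusted p = 0.862 with an estimated correlation). Its median was -0.96 without the first mutant immunoprecipitate and -0.37 without the second. That list also missed the preset test without the second mutant immunoprecipitate, at an adjusted p of 0.140 (0.00251 to 0.405 over its alternatives), and without both wild-type libraries numbered 1, at 0.0568. Secretory and membrane mRNAs gave 23 higher and 1 lower of 35 (26 and 2 adjusted over the list alone), median 1.97, with HSPG2 at 2.95, LAMA5 at 2.64 and COL4A2 at 2.55. It was the only list in either immunoprecipitate to hold with an estimated correlation (adjusted p = 0.0363), and it missed the threshold by that test after the length correction (0.394) and the GC correction (0.162).

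Large increases were again seen in EPPK1 (3.40 ± 0.45), BCL9L (3.38 ± 0.67), PLEC (3.22 ± 0.91), FLNC (3.05 ± 0.36), SETD1B (3.01 ± 0.43) and TNRC18 (2.96 ± 0.40), and decreases in TCEAL8 (-5.23) and MTRNR2L2 (-5.68), the latter uncertain for the reason given for MTRNR2L8. SSB changed by -1.42 ± 0.42 (edgeR adjusted p = 0.0352) and LAMB1 by 1.35 ± 0.42 (edgeR adjusted p = 0.0395). The other 7 mRNAs linked to La lay between -0.85 for MDM2 and 1.20 for HSPA5 and did not pass. UBA2 was at -1.79 and RANBP2 at 1.64, with 3 higher and 5 lower of 18 in the SUMO pathway. In the lists that did not pass camera's test JAK1 was at 1.32, LIFR at 1.46, PTPN2 at -1.84, MCM6 at 1.97, PCNA at -1.73, ATF4 at -1.99, SEL1L at 1.33, IFIT5 at -1.90, LARP7 at -1.61, SREBF2 at 1.69, HSPA1B at 1.71, HSPB1 at -2.06, ZNF646 at 2.32 and ZNF703 at 2.31. Spearman's rho of log2 change with length was 0.548. With length removed 2512 genes passed, the ribosomal protein median moved to -1.003, the OXPHOS median to -0.63 and the secretory median to 1.21, and the histone median turned to 0.61, at which the histone and TOP lists missed camera's preset test (adjusted p = 0.0692 and 0.405). Of 40 named calls 18 ended when some single library was left out, in ATF4, BCL9L, COL4A2, HSPA1B, JAK1, LAMB1, LARP7, LIFR, MCM6, PCNA, PLEC, PTPN2, RANBP2, SEL1L, SREBF2, SSB, UBA2 and ZNF703, and 13 ended under the length correction, among them HSPG2, HIST1H3B, HIST1H2BJ, HSPB1, PLEC and SSB. Without the second mutant immunoprecipitate RANBP2 was at 1.02, LIFR at 0.86 and SSB at -2.13. Among the 18 were SSB (adjusted p = 0.0909 without the first mutant input, 0.190 without the second and 0.138 without the first mutant immunoprecipitate, 0.00350 to 0.227 over its alternatives) and LAMB1 (0.254 without the first input, 0.0902 without the second and 0.200 without the second immunoprecipitate, 0.00279 to 0.256 over its alternatives).

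**Figure D2:**
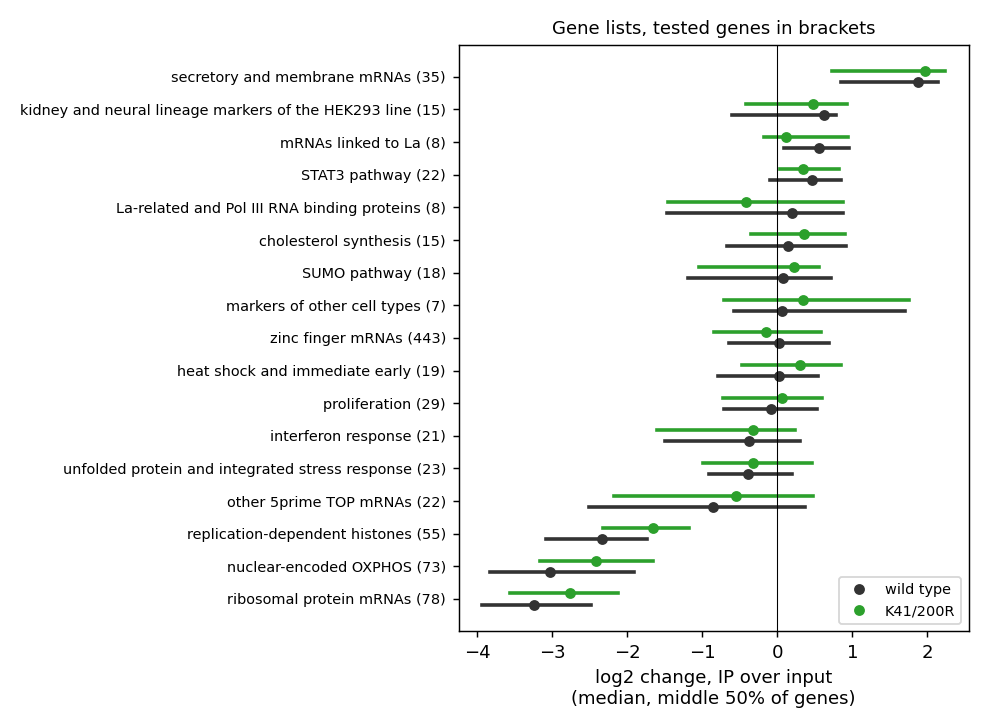
Median (point) and middle 50% (bar) of the log2 change of immunoprecipitate over input for each gene list, for wild-type (black) and K41/200R (green) gfp-La, with the number of tested genes in brackets. Ribosomal protein, OXPHOS and histone mRNAs have medians of -3.24, -3.03 and -2.34 with the wild type and -2.76, -2.42 and -1.66 with the mutant.

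The third comparison addresses the series' question, whether recovery of RNA differed between the proteins. No gene passed at this depth and number of libraries, which does not show equal recovery. By edgeR 0 of 13657 genes passed, with 32 at an unadjusted p under 0.05, and by DESeq2 0 passed, with 19. Among genes with a mean of at least 10 CPM the smallest unadjusted values belonged to HIST2H2AC (log2 difference 1.20 ± 0.45), ATP5L (1.00 ± 0.42), HIST1H2AD (1.04 ± 0.45), RNF181 (1.28 ± 0.56) and HIGD2A (1.03 ± 0.45) on the side of higher recovery with the mutant, and to ZNF92 (-0.96 ± 0.54) and KBTBD8 (-0.94 ± 0.55) on the other. Without the first mutant immunoprecipitate RNF181 was at 0.80, HIGD2A at 0.66 and ZNF92 at -0.61 (-1.53 without the second), and KBTBD8 was at -0.54 without the second wild-type input and -1.49 without the first. SSB differed by 0.57 ± 0.58, which turned to -0.15 without the second mutant immunoprecipitate. The 8 mRNAs linked to La lay between -0.81 for BCL2 and 0.10 for HSPA5. Among 9258 genes with a mean of at least 10 CPM the middle 95% of differences ran from -0.48 to 0.61, with a median SE of 0.51. In simulated data this test recovered 5 of 70 genes with a 4-fold difference and 58 of 70 with a 16-fold one. It thus missed most differences of 4-fold. Simulated libraries were drawn independently, as the test assumes. In the data, deviations from group means correlated between input and immunoprecipitate, at 0.66 with the wild type and 0.35 with the mutant. The 32 genes are below a share of 0.05 of those tested, so the test was stricter than its nominal level. With the sample number as a block 0 genes passed, with 152 at an unadjusted p under 0.05.

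The 2 enrichments, which share no library, had a Pearson r of 0.924 and a Spearman's rho of 0.944 across genes, which are not independent replicates, with a slope of mutant on wild type of 0.896. Both proteins gave 1473 genes called higher, against 220.8 for independent lists, and 1993 called lower, against 397.3, and 0 in opposite directions. Independence is a weak reference here, since both enrichments used the same antibody and both followed transcript length (Spearman's rho 0.607 and 0.548). Without a gfp-alone immunoprecipitate the excess does not show that both proteins bind alike. A further 760 genes were called with the wild type and 446 with the mutant without a call for the other, which does not show that they differ. Genes called the same way with both numbered 3466, and 2291 without the second wild-type input, 1061 and 1522 without the first and second mutant inputs, and 1803 without the second mutant immunoprecipitate. By list, camera's preset test of the difference passed for ribosomal protein (median 0.47), other TOP (0.24), histone (0.73) and OXPHOS mRNAs (0.46), all less depleted with the mutant, and for zinc finger mRNAs (-0.14). None of the 5 passed with an estimated correlation (adjusted p = 0.748, 0.818, 0.468, 0.748 and 0.793 in that order) or with fry. Without 1 library the ribosomal protein median ran from 0.13 to 0.72 and the OXPHOS median from 0.17 to 0.82, lowest without the first mutant immunoprecipitate, and the histone median from 0.42 to 1.14, lowest without the second wild-type one; each was highest without the first wild-type one. The TOP list missed the preset test without the second input of either line or without either wild-type immunoprecipitate (0.113 to 0.589), and its median turned to -0.06 without the first mutant one. The zinc finger list missed it without the second wild-type input (0.248) and the first mutant immunoprecipitate (0.866), and its median turned to 0.07 without the second wild-type immunoprecipitate.

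**Figure D3:**
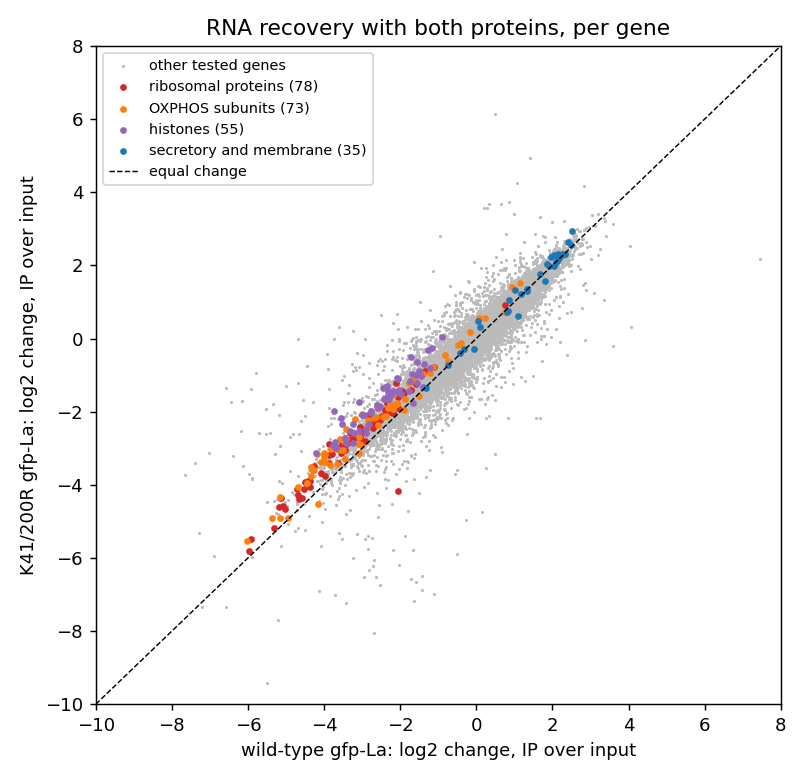
Log2 change of immunoprecipitate over input for each of 13657 genes with wild-type (horizontal) and K41/200R (vertical) gfp-La, with 4 gene lists in colour and a dashed line of equal change. Depleted ribosomal protein, OXPHOS and histone mRNAs lie mostly above the line, with median differences of 0.47, 0.46 and 0.73.

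The fourth comparison set the input RNA of the lines side by side. GPR50, an orphan G protein-coupled receptor, had 2825 and 2035 counts in wild-type input and 0 in both mutant inputs, at least 1318-fold lower with a floor of 3 counts over the group. SULT1C4, a sulfotransferase, had 0 counts in both wild-type inputs and 75 and 42 in the mutant ones, at least 47.9-fold higher. LGALS1, the lectin galectin-1, was at 180.1 ± 84.1 CPM in the wild-type line and 13.0 ± 1.04 CPM in the mutant line, a log2 change of -3.79 ± 0.41 (edgeR adjusted p = 0.0341). In all, 15 genes passed, 1 higher (SULT1C4) and 14 lower in the mutant line, with 1377 at an unadjusted p under 0.05. The other lower genes were S100A16 (-6.08 ± 0.80), HIST1H2BM (-5.51 ± 0.62), SNURF (-5.18), HIST1H2AJ (-5.18 ± 0.56), TCIRG1 (-4.51), SLC16A3 (-4.25), the interferon-induced IFITM3 (-3.88 ± 0.51), SOCS3 (-3.65), an inhibitor of cytokine signalling, PLAU (-3.64 ± 0.48), which encodes urokinase, SLCO4A1 (-3.53 ± 0.41), GFPT2 (-3.51 ± 0.48) and ID1 (-2.81 ± 0.37). SNURF shares a transcript with SNRPN and the histone genes have near-identical copies, so these values are uncertain.

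DESeq2 called 352 genes, which included these 15. With the sample number as a block 1829 genes passed, which also included them, but the labels do not say what the number marks. Without the second wild-type input, either mutant input or either mutant immunoprecipitate 1 gene passed, GPR50, while 123, 135 and 98 passed without the first wild-type input and the first and second wild-type immunoprecipitates. Without both wild-type libraries numbered 1, 1129 genes passed, which included the 15. Below the threshold, higher values in the mutant line had their smallest p in LAMA2 (2.54 ± 0.40, edgeR adjusted p = 0.0654) and ZNF793 (2.51 ± 0.47, edgeR adjusted p = 0.112). CCND1, the cyclin D1 gene, was at 83.3 ± 57.3 and 12.3 ± 5.94 CPM (-2.77 ± 0.74, edgeR adjusted p = 0.215), MYC at 99.4 ± 17.7 and 33.1 ± 8.07 CPM (-1.58 ± 0.33, edgeR adjusted p = 0.132), STAT3 at -0.71 ± 0.34 and SSB at 0.78 ± 0.41, none past the threshold. CCND1 was at -1.81 without the second wild-type input and SSB at 0.49 without the second mutant input. Camera's preset test passed for lower medians in the STAT3 pathway (-0.41, 1 of 22 called, 5 adjusted over the list alone), histones (-0.31, 2 of 55, 11), interferon response (-0.62, 0 of 21, 2), heat shock and immediate early genes (-0.70, 0 of 19, 5) and ribosomal proteins (-0.19, 0 of 78, 0), and for a higher one in zinc finger mRNAs (0.26, 0 of 443, 0). For histones the mean was -1.03, and the median was -0.16 without the first wild-type input and -0.19 without the second mutant one. The heat shock median was -1.08 without the first mutant input, and the ribosomal protein median was -0.40 without the first mutant input and -0.0050 without the second. None of the lists passed with an estimated correlation (adjusted p = 0.341, 0.595, 0.341, 0.208, 0.878 and 0.595 in that order), and the ribosomal protein list missed the preset test under upper quartile scaling (adjusted p = 0.0684, 7.54e-05 to 0.807 over its alternatives), without the first wild-type input (0.737), without the second mutant input (0.807) and without either wild-type immunoprecipitate (0.0709 and 0.0624).

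**Figure D4:**
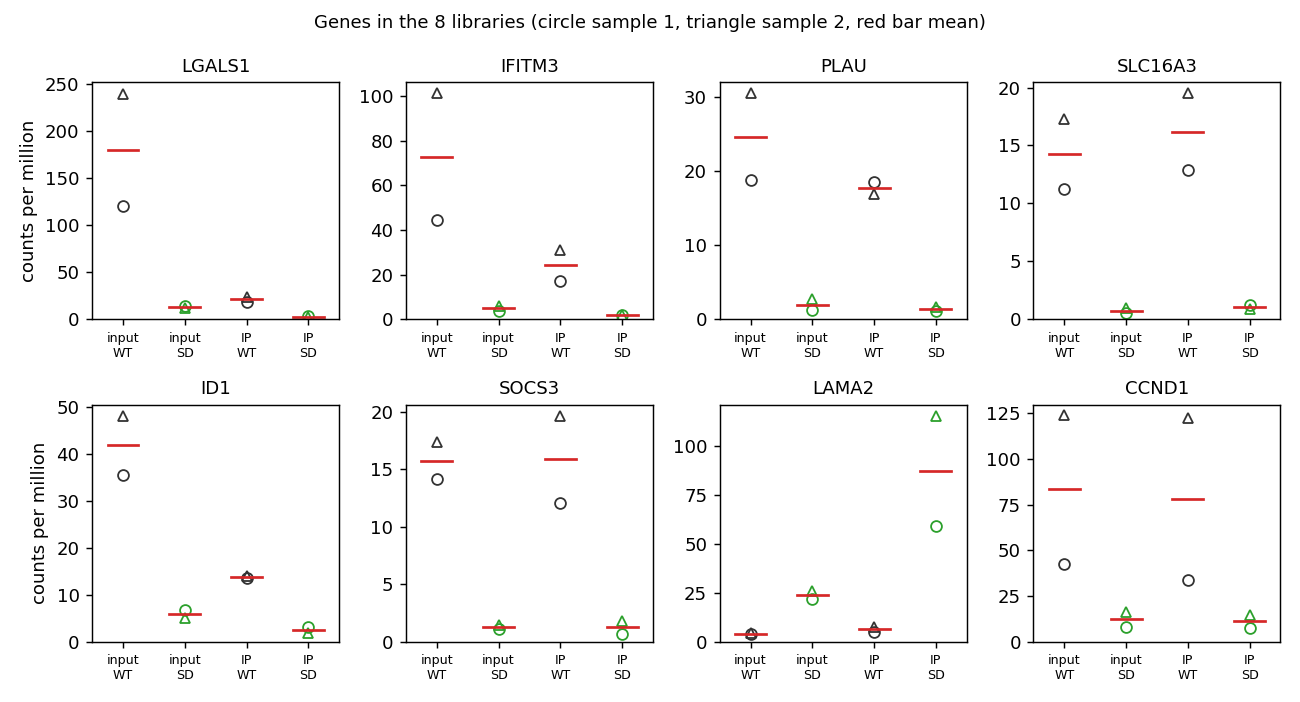
CPM of 8 genes in input and immunoprecipitate of the wild-type (WT, black) and K41/200R (SD, green) lines, with sample 1 as circles, sample 2 as triangles and the mean of n = 2 as a red bar; each panel has its own vertical axis from 0. LAMA2 and CCND1 did not pass the test in input, and the other 6 genes did.

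Between the immunoprecipitates 1 gene passed, GPR50, with 2168 and 2210 counts with the wild type and 1 in each mutant library. The ratio was 1978 with a counting interval of 547 to 16340. At an unadjusted p under 0.05 there were 1224 genes, and DESeq2 called 279. All 15 genes that differed in input had the same direction here and an unadjusted p under 0.05, and across genes the line differences in input and in the immunoprecipitate had a Pearson r of 0.843. Without the first wild-type immunoprecipitate 146 genes passed, without either wild-type input 10, without the first mutant immunoprecipitate 2, and without both wild-type libraries numbered 1, 983.

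In the authors' deposited table for the wild type 1740 genes were higher and 1974 lower at an adjusted p under 0.05, of 12446 with an adjusted p. In the authors' deposited table for the mutant 2763 were higher and 2643 lower of 13166. For RPS12 the authors' deposited tables gave log2 changes of -5.61 and -5.57, and for SSB -1.83 and -1.31. The authors' values come from DESeq2 in a separate table for each line and appear shrunken in size. Those above come from a joint edgeR fit, so sizes and numbers of calls are not directly comparable.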

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

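The tests of mixed cells, and of a batch for genes high in the mutant, were chosen after their results were seen, as were the length and GC corrections of the values below, the comparison of the matched genes' lengths and the resampling of genes and regions; the other tests were set out beforehand. A difference between the proteins appeared for 5 gene lists by camera's preset test of the difference itself. The median log2 difference of enrichment, mutant minus wild type, was 0.47 for ribosomal protein mRNAs, 0.24 for other TOP mRNAs, 0.73 for replication-dependent histones, 0.46 for OXPHOS mRNAs and -0.14 for zinc finger mRNAs. With an estimated correlation none of them passed, and no biological explanation of them was tested. After the length correction the medians were 0.20, 0.15, 0.43, 0.23 and -0.14, and the TOP list missed the preset test (adjusted p = 0.208) while the other 4 passed it. After the GC correction they were 0.45, 0.25, 0.69, 0.43 and -0.11. All 5 then passed the preset test and none passed with an estimated correlation (adjusted p = 0.206 to 0.878). Across all genes the difference itself followed length (Spearman's rho -0.310) and GC content (0.333), so part of these medians is not particular to the lists.

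The first pattern is the depletion of ribosomal protein mRNAs in both immunoprecipitates. GC content alone is argued against, since the wild-type median differed by -3.90 from the lower 2.5% bound of lists matched on GC content and expression, and the mutant median lay at percentile 0 of such lists as well. Transcript length stays open: the list's median was at percentile 0 of 10000 lists matched on length and expression with both proteins, but the matched genes were longer (median 915.5 against 738.3 nt), and after the length correction, which moved its median from -3.24 to -1.20 and from -2.76 to -1.003, the list missed the threshold with an estimated correlation (adjusted p = 0.398 and 0.394), as it had before the correction (0.198 and 0.299), though it passed camera's preset test (7.90e-22 and 1.02e-15). Reads shared with pseudogene copies also stay open, with a Spearman's rho of -0.165 between change and pseudogene number with the wild type and -0.225 with the mutant. Nonspecific recovery of long RNA and a preference of La cannot be weighed against each other without a gfp-alone immunoprecipitate, which was not analysed here.

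The second pattern is the set of 15 genes that differed between the lines in input. Gain or loss of the surrounding region by at least 0.5 on the log2 scale, the bound set beforehand, is argued against as a cause for the set. The median change of the 10 nearest tested neighbours, in the direction of the call, was 0.30 over the 15 genes. Over 14 regions, with both histone genes as 1 region, it was 0.33 (interval over resampled regions 0.20 to 0.47). That interval also lies above 0, so a smaller regional change is not argued against. The neighbours of ID1, IFITM3 and SLCO4A1 had medians of 0.52, 0.65 and 0.81, and adjacent genes over the genome had an r of 0.1704 against at most 0.0280 in 1000 shuffled orders, so regional change in part of the genome stays possible, as does loss of a single gene. The mutation and the derivation of each stable line coincide, so an effect of La sumoylation stays open and untested.

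The third pattern is that wild-type sample 1 lay between wild-type sample 2 and the mutant line. These wild-type samples also differed in reads with more than one alignment. They were 30.4% in sample 1 against 10.9% in sample 2 for input, and 21.2% against 5.92% for the immunoprecipitate. Whether that difference bears on the pattern was not tested. A mixture with mutant cells as the whole cause would give every gene 1 share. Genes picked in the immunoprecipitate were used for input. Those low in the mutant put the share 37.5 percentage points above those high in the mutant (interval over resampled genes 26.6 to 41.6). The intervals also lay above 0 in the immunoprecipitate and with genes picked in the same fraction. Genes were picked by their level in wild-type sample 2, which also enters the share. Deviations from group means correlated at 0.66 between wild-type input and immunoprecipitate. Picking in either fraction can thus raise the share from low genes, so the test does not decide. A batch shared by the samples numbered 1 was also tested on genes high in the mutant, 13 picked in the immunoprecipitate and 9 picked in input. For the 13, sample 1 over sample 2 had a median log2 ratio of 0.090 in mutant input against 1.68 in wild-type input. The ratio of the changes stayed under 0.5 in both fractions (highest upper bound 0.229). Picking by a low level in wild-type sample 2 can raise the wild-type change alone, so this test does not decide either. Over all tested genes, deviations of same-numbered samples correlated at 0.43 between inputs and 0.56 between immunoprecipitates. A mixture stays open, with shares of 34.97% in input and 35.9% in the immunoprecipitate from high genes and 72.3% and 71.8% from low ones. However, GPR50 was higher in wild-type sample 1 than in sample 2, which a mixture with mutant cells would lower. SULT1C4 had 0 counts in wild-type input 1, where the share of 34.97% would bring 27.4. For genes low in the mutant a shared batch stays open too, with a median log2 ratio of -0.77 in mutant input against -1.63 in wild-type input, and ratios of the changes of 0.472 (0.344 to 0.601) in input and 0.425 (0.349 to 0.503) in the immunoprecipitate that span the bound of 0.5.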

How the results depend on the processing

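The length and GC corrections and the fit without both wild-type libraries numbered 1 were chosen after seeing the data. The difference of enrichment gave 0 genes under every alternative run. The pseudocount alternative was not run, since the tables hold counts. Where no cause is named below, the cause was not tested. Of the values of named genes under alternatives 1935 stayed on the same side of the threshold with the same direction, 221 fell below it, 40 rose above it and 2 reversed; of list medians 338 stayed, 19 fell below and 4 reversed.

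For wild-type immunoprecipitate against input 4226 genes became 2549 to 3973 without 1 library, 2587 with a minimum fold of 1.5, 2323 with only the libraries compared and 2309 with the length correction. For the mutant 3912 became 1073 to 4614 without 1 library, 2368 with the minimum fold and 2512 with the length correction. For input against input 15 became 262 with no filter on low counts, 7 with at least 10 CPM in 2 libraries, 1 to 135 without 1 library, 8 with the minimum fold, 1 with only the libraries compared, 352 with DESeq2 and 1129 without both wild-type libraries numbered 1. For immunoprecipitate against immunoprecipitate 1 became 2 with upper quartile scaling, 2 with library size alone, 170 with no filter, 1 to 146 without 1 library, 279 with DESeq2 and 983 without both wild-type libraries numbered 1. Fewer libraries leave fewer residual degrees of freedom, and a lone library was assumed to vary like the other groups. With only the libraries compared, 5434 genes passed for the mutant against 2323 for the wild type. The fit of all libraries had the reverse order, 3912 against 4226, so which protein had more calls depended on sharing 1 estimate of the spread.

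In the labels samples share only a number, but same-numbered samples deviated alike in the data. Deviations from group means correlated at 0.66 between wild-type input and immunoprecipitate, 0.35 between the mutant ones, 0.43 between inputs and 0.56 between immunoprecipitates. With the number as a replicate block 6914, 6559, 1829 and 1006 genes passed in the order above, and 5889 were called the same way with both proteins.

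Lists past the threshold went from 5 to 3 with the length correction, 0 with an estimated correlation and 17 with fry's mixed test for the wild type, and to 3, 1 and 17 for the mutant. Directional fry passed for ribosomal protein, TOP, histone, OXPHOS and secretory mRNAs with both proteins. Its adjusted p-values were 0.00278, 0.0124, 0.00290, 0.00286 and 0.00278 for the wild type. For the mutant they were 0.00408, 0.0212, 0.0189, 0.00754 and 0.00175. For the difference the number ran from 3 to 8 without 1 library, and was 0 with an estimated correlation, 0 with directional fry and 0 with mixed fry. For input against input it was 0, 0 and 3, and for immunoprecipitate against immunoprecipitate 0, 0 and 0, with 4 to 9 without 1 library. The correlation of both enrichments, 0.924, was 0.675 with no filter, 0.977 with at least 10 CPM, 0.808 to 0.906 without 1 library and 0.858 without both wild-type libraries numbered 1. The 3466 genes called the same way in both became 1061 to 3141 without 1 library, 2288 with only the libraries compared and 1966 with the length correction.

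Under the length correction the histone medians reversed to 0.13 and 0.61 and HSPB1 with the wild type to 0.10. For the difference of enrichment without 1 library, the TOP median ran from -0.056 to 0.45, with the reversal without the first mutant immunoprecipitate; the zinc finger median ran from -0.30 to 0.071, reversed without the second wild-type immunoprecipitate; and SSB ran from -0.15 to 1.005, reversed without the second mutant immunoprecipitate.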

Other observations

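No test in this part was chosen after its result was seen. In the immunoprecipitates, mutant against wild type, 3 of the 5 lists that lay lower in mutant input had medians below 0 as well, and ribosomal proteins and histones had medians above 0. The median log2 difference was -0.62 for the STAT3 pathway (0 of 22 genes called, 3 lower adjusted over the list alone), -0.62 for heat shock and immediate early genes (0 of 19, 3 lower) and -0.68 for interferon response genes (0 of 21, 3 lower). For the interferon list the median was -0.46 with genes at 0 counts in a group set to their bound. These lists passed camera's preset test (adjusted p = 9.31e-05, 0.00015 and 0.00015) and missed it with an estimated correlation (adjusted p = 0.348 for each). Ribosomal protein and OXPHOS mRNAs had medians of 0.27 and 0.27 (camera adjusted p = 0.0141 and 0.00252, and 0.958 for both with an estimated correlation). For histones the median was 0.38 and the mean -0.28, and the list did not pass.

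SOCS3 was the 1 gene of the STAT3, interferon and heat shock lists called over all genes in input, and the genes that follow did not pass. OAS3, an interferon-induced synthase of 2'-5' oligoadenylate, was at 44.5 ± 23.4 CPM in wild-type input and 5.85 ± 0.470 CPM in mutant input (edgeR adjusted p = 0.112), and at 130.7 ± 85.4 and 11.6 ± 0.766 CPM in the immunoprecipitates (SD, n = 2; edgeR adjusted p = 0.116). HSPB1, a small heat shock protein, was at 65.3 ± 25.9 and 24.3 ± 2.94 CPM in input (edgeR adjusted p = 0.159), and IER3, an immediate early gene, at 17.5 ± 2.41 and 5.56 ± 0.342 CPM (edgeR adjusted p = 0.128). LAMA5, a laminin chain, was at 91.1 ± 34.8 and 28.1 ± 5.32 CPM in input, a log2 change of -1.70 ± 0.35 (edgeR adjusted p = 0.136), while LAMA2, another laminin chain, lay on the opposite side at 4.12 ± 0.296 and 24.0 ± 2.78 CPM. SSB, whose reads include the transgene's, was at 338.7 ± 9.83 and 582.9 ± 152 CPM in input and at 85.5 ± 10.7 and 218.1 ± 120 CPM in the immunoprecipitates.

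Wild-type input 1 had a Pearson r of log2 CPM across genes of 0.957 with wild-type input 2 and of 0.960 and 0.958 with the mutant inputs. The first wild-type immunoprecipitate had 0.947 with the second and 0.967 and 0.953 with the mutant ones. Within the mutant line r was 0.980 between inputs and 0.966 between immunoprecipitates. Genes are not independent replicates of one another.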
